A study of Mus musculus with 24 samples.

How the data were processed

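Polyadenylated RNA was sequenced from organoids, three-dimensional cultures grown from pancreatic epithelium, that came from mice of 4 genotypes aged 13 weeks. All carried KrasG12D and p53R172H alleles (KP). KPC added Ptf1a-Cre, a recombinase driven from the promoter of a pancreatic transcription factor gene. KPS added a floxed allele of the splicing factor gene Sf3b1 without Cre, and KPCS added both. The labels give the Sf3b1 allele as heterozygous in one place and as homozygous floxed in another, so the number of floxed copies was left open. Each culture was kept at 21% oxygen (normoxia) or at 3% oxygen (hypoxia). The design text names 3 organoids per group as biological replicates. The organoid numbers were 571, 616 and 625 in KP and KPC, and 520, 528 and 530 in KPS and KPCS. Of the 24 libraries in the labels, 23 had a column of values. The normoxic library of KPS number 530 was not analysed here, so that group had n = 2.

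The main table held expression values of 16488 genes per library on a log2 scale, deposited by the authors, with values from 0.491 to 19.352. How these values were normalized is not given in the sources used here, and they were used as deposited, with no pseudocount. Reads were processed with STAR 2.4.2a, Picard, featureCounts and Subread 1.5.0, per the submitters' processing notes, which name the mouse build mm8. The genes carried Ensembl identifiers, and the coordinates printed here come from the GENCODE annotation of GRCm38, not from mm8. A symbol was given for 14015 genes. Of the 2473 without a symbol, 2435 were named from the annotation by identifier, and 20 symbols that a spreadsheet had turned into dates were replaced in the same way. No read counts per library were analysed here, so depth is unknown, and no counting interval or detection floor is given. Whether the counting used strand is not given either, so overlapping and antisense genes could not be told apart. A second deposited table held the authors' own tests of 10 comparisons, with log2 fold changes and adjusted p-values. It was used for description only, at an adjusted p threshold of 0.01.

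Genes were tested with limma 3.58.1 in R 4.3.3 on the log2 values, in 1 fit over 8 groups and 23 libraries with 15 residual degrees of freedom, with the trend and robust settings. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were counted as changed. All 16488 genes were tested. Errors of log2 differences are standard errors from this fit, and errors of group means are standard deviations. The comparisons were hypoxia against normoxia in each genotype, KPC against KP, KPCS against KPS, KPCS against KPC and KPS against KP at each oxygen level, and 4 differences of differences. In all, 32 gene lists were tested with limma's camera test, once with its preset correlation between genes of 0.01 and once with the correlation estimated from the data. Adjusted p-values of lists are those of the preset correlation unless stated otherwise. A HIF target score was the mean log2 value of the measured members of the HIF target list. Its change per organoid line was compared between genotypes with a two-sided exact permutation test. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

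The comparisons, the lists, most of the alternative settings and the rule for naming genes were fixed before the data were examined. The rule took 6 fixed genes (Sf3b1, Kras, Trp53, Ptf1a, Hif1a and Epas1). It took the 8 largest rises and the 8 largest falls per comparison among changed genes. These had to have a mean at or above the median of gene means (9.039) and groups that did not overlap, and predicted genes, ribosomal protein copies and repeated symbols were left out. Differences of differences went without the condition on overlap. It also took up to 4 members of each list with the smallest p. Ptf1a was not analysed here. A gene named outside the rule is marked as chosen after its values were seen.

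The normoxic and hypoxic libraries of a genotype with the same number were taken to come from the same organoid line, since the design treats organoids as the replicates. The fit with the line as a block is given beside gene counts and list tests of hypoxia where it moved them. Counts of list members that passed are from the fit without a block in every genotype. The check of this pairing gave correlations of deviations from the group means, across genes, of 0.783, 0.839 and 0.715 in KPC, 0.602 and 0.443 in KPS, 0.437, 0.558 and 0.324 in KPCS, and 0.691 in KP 571. KP 616 and KP 625 gave -0.071 and -0.006, so the data do not bear out the pairing of these 2 lines. Normoxic KP 625 correlated with hypoxic KP 616 at 0.625, and normoxic KP 616 with hypoxic KP 625 at 0.004. A block with these 2 hypoxic libraries exchanged was added after the data were examined. In 18 of 22 libraries the best match carried their own number. The labels do not say what a number shared between genotypes without and with Cre stands for. Of those 4 comparisons only KPCS against KPS in hypoxia had 3 pairs that all correlated above 0.1 (0.447, 0.516 and 0.407), so the fit with the number as a block is given beside it, a choice made after its count had been seen. The most similar 2 libraries correlated at 0.993 across genes, and replicates differed by a mean absolute log2 difference of 0.245 to 0.651, so no library was treated as a copy of another.

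The tests were run on simulated data before use. With 100 of 16488 genes changed per size and 3 libraries against 3, simulated as hypoxia against normoxia in KP, 55% of genes changed by a log2 difference of 1 and 91% of those changed by 2 were recovered, with 5 other genes called. For KPCS against KPC in normoxia the shares were 52% and 91%, with 7 other genes called. For the difference between the hypoxia responses of KPCS and KPC they were 17% and 76%, with 2 other genes called. These data were simulated without an effect of the line. In other data simulated with a line effect and fitted with the line as a block they were 43% and 79%, with 11 other genes called. The 2 results thus differ in the data as well as in the fit. All groups were simulated with the same spread per gene. Alternatives were quantile normalization, centring of each library on its median, a filter at the 25th percentile of mean expression, limma without trend and robust settings, a log2 difference of at least 1, fits on the compared groups only, replicate blocks, and leaving out each library in turn. Fits without organoid number 530 were added after the data were examined.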

Results

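Expression of 16488 genes was compared between organoids of 4 genotypes at 21% and at 3% oxygen, with 3 libraries in each of 8 groups except normoxic KPS, which had 2. KP organoids carried mutant Kras and p53 alleles, KPC carried these with Ptf1a-Cre, KPS carried them with a floxed Sf3b1 allele, and KPCS carried all of these. The lines therefore differ by label in the Cre driver and the floxed Sf3b1 allele, and each was compared at both oxygen levels. Whether the mutant Kras and p53 alleles are expressed without Cre was not tested here. Lines with and without Cre may thus also differ in the expression of these alleles. The term Cre effect below names a comparison of lines with and without Cre. All values are on the authors' normalised log2 scale, and sequencing depth is unknown. P-values of limma rest on 1 estimate of spread per gene over all 8 groups, from organoids named as biological replicates. Without a block they treat the 2 libraries of a line as independent. Groups differed in spread: the SD of the HIF target score was 0.196 and 0.113 in KP and 0.648 and 0.631 in KPCS, in normoxia and hypoxia. Fitted on the compared groups only, hypoxia gave 2305 and 899 genes in KP and KPC, and 0 in both KPS and KPCS. KPCS against KPC then gave 1 gene in normoxia and 0 in hypoxia.

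All groups had an epithelial, ductal profile. The mean log2 value of ductal markers ranged from 12.33 (KPC in hypoxia, SD 0.32, n = 3) to 12.70 (KPCS in normoxia, SD 0.22, n = 3). Acinar markers ranged from 3.12 to 3.52 between groups, fibroblast and stellate cell markers from 3.39 to 4.16, and endothelial markers from 4.22 to 4.91. Markers of immune cells ranged from 5.97 in normoxic KP to 6.85 in hypoxic KPCS, endocrine markers from 4.31 to 6.14 and markers of gastric metaplasia from 8.25 to 9.02. The median over all genes of their mean values was 9.04.

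The first principal component carried 29.6% of the variance and the second carried 23.0%. KP libraries lay between -60.1 and -41.1 on the first component. The KPC lines 571 and 625 lay between 22.8 and 45.2, while KPC 616 lay at -15.3 in normoxia and -1.1 in hypoxia. The hypoxic library of KPS 530 lay at -43.1, among the KP libraries on this axis. Most hypoxic libraries lay below 0 on the second component, with the hypoxic library of KPCS 528 at 23.7 as an exception.

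**Figure D1:**
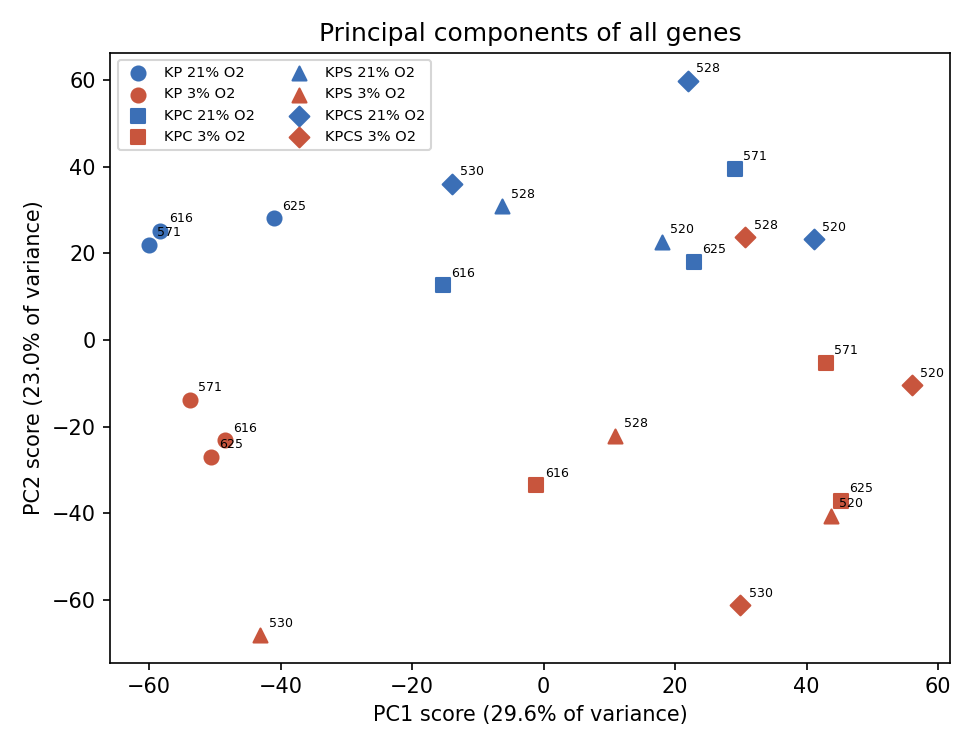
Scores of the 23 libraries on the first principal component (horizontal axis, 29.6% of variance) and the second (vertical axis, 23.0% of variance), computed over 16488 genes. Marker shape gives the genotype, colour gives the oxygen level (21% or 3%) and the number beside each marker names the organoid. KP libraries lie at -41.1 or lower on the horizontal axis.

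Sf3b1 encodes a core subunit of the SF3b complex, which recognises the branch point of introns as part of the U2 small nuclear ribonucleoprotein. The gene (ENSMUSG00000025982) lies on chromosome 1 from 54985169 to 55027481 in GRCm38. Its mean log2 value in KPCS was 13.33 ± 0.39 in normoxia and 13.84 ± 0.28 in hypoxia (SD, n = 3 each). In KPS it was 14.10 ± 0.39 in normoxia (SD, n = 2) and 14.48 ± 0.46 in hypoxia (SD, n = 3). KPCS was lower than KPS by a log2 difference of -0.77 ± 0.25 in normoxia, 0.587-fold, and of -0.64 ± 0.22 in hypoxia (SE). Neither difference passed the threshold in limma, with adjusted p = 0.219 and 0.272. Against KPC the difference was -0.62 in normoxia (adjusted p = 0.240) and -0.42 in hypoxia (adjusted p = 0.620). In normoxia the KPCS libraries stood at 13.05 (520), 13.78 (528) and 13.16 (530), and the KPS libraries at 14.37 (520) and 13.82 (528). The authors' deposited table gave -0.94 (adjusted p = 0.0520) in normoxia and -0.83 (adjusted p = 0.0595) in hypoxia for KPCS against KPS. A whole-gene value does not separate a recombined from an intact allele.

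**Figure D2:**
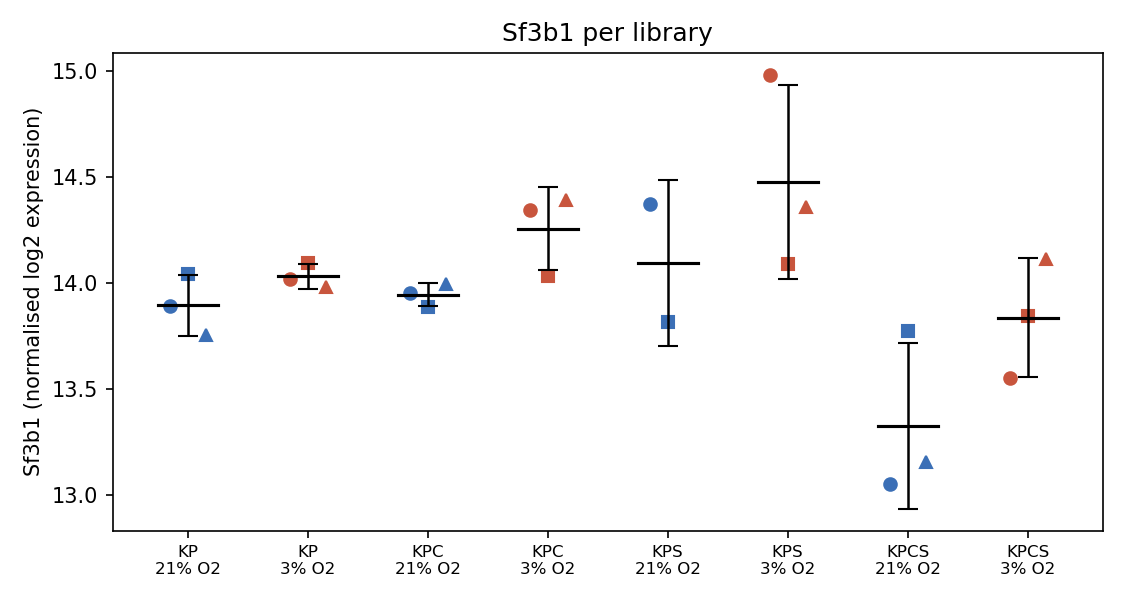
Normalised log2 expression of Sf3b1 (vertical axis) in each library by genotype and oxygen level (horizontal axis), with horizontal bars for group means and error bars for the SD. Circle, square and triangle mark the 3 organoid numbers of a genotype in ascending order. The KPCS libraries in normoxia lie at 13.05, 13.78 and 13.16.

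None of the other fixed genes measured changed in any comparison at the adjusted threshold. Trp53 stood at 12.32 ± 0.40 in KPCS in normoxia (SD, n = 3), a log2 difference of 1.32 to KPS (n = 2) (limma adjusted p = 0.124). Epas1, which encodes the hypoxia-inducible factor HIF-2α, was 0.71 higher in hypoxic than in normoxic KP (adjusted p = 0.123). With the line as a block this difference passed, with adjusted p = 0.0404, and the difference of Sf3b1 between hypoxic and normoxic KPCS, 0.51, went from adjusted p = 0.166 to 0.0353. Hif1a means lay between 11.92 and 12.67, and Kras means between 11.025 and 11.686.

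Hypoxia was compared with normoxia within each genotype, starting with KP. In KP, low oxygen raised genes of the HIF response and of glycolysis and lowered genes of DNA replication. Of 57 measured HIF targets, 39 rose and none fell (49 adjusted over the list alone), with a median log2 change of 1.58. The largest rises included Eno2, a glycolytic enolase, at 3.73 ± 0.85 (SE, adjusted p = 0.0191), Ankrd37, a known HIF target, at 3.63 ± 0.48 (adjusted p = 0.00146), Adm, the precursor of adrenomedullin, at 3.61 ± 0.81 (adjusted p = 0.0173), and Bnip3, a mitophagy receptor, at 3.31 ± 0.58 (adjusted p = 0.00534). Cyp2s1, Ak4, Unc13a and Ndrg1 also rose by 3.02 to 3.43. Of 20 glycolytic genes, 15 rose (19 over the list alone), among them Pfkl (1.97), Aldoc (2.60), Pkm (1.26) and Eno1 (1.29). Collagen-modifying enzymes rose in 4 of 19 measured members, Plod2 (2.30), P4ha1 (2.03), P4ha2 (2.16) and P4hb (1.08).

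Of 28 genes of DNA replication in KP, 22 fell (26 adjusted over the list alone), with a median of -1.46. Rrm2, a subunit of ribonucleotide reductase, changed by -1.75 ± 0.32 (adjusted p = 0.00647), Mcm6, a subunit of the replicative helicase, by -1.78 ± 0.36 (adjusted p = 0.0119), while Clspn, a replication checkpoint adaptor outside this list, changed by -1.87 ± 0.37 (adjusted p = 0.0103). Of 24 mitotic genes 5 fell, among them Plk1 (-1.25), and all 24 fell when adjusted over the list alone. Cholesterol synthesis genes rose in 7 of 24 members (17 over the list alone), such as Lss (1.60), Mvd (1.78) and Tm7sf2 (1.74). Fatty acid synthesis genes rose in 3 of 14, Scd1 (1.68), Acss2 (2.13) and Acacb (1.88). Splicing factors were lower: 5 of 17 genes of the SF3b complex and U2 particle fell (8 over the list alone), such as U2af1 (-0.63) and Sf3b3 (-0.52), and 3 of 32 other spliceosome genes fell (10 over the list alone), such as Snrpd1 (-0.93).

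In limma, 340 genes rose and 412 fell in KP under hypoxia, 752 in all, of which 45.2% were higher, and 54% after median centring, and with the line as a block 2772 genes changed (1346 higher, 1426 lower). The camera test called the lists of HIF targets (5.16e-39), glycolysis (5.18e-23), replication (3.69e-25), mitosis (5.73e-16), cholesterol synthesis (1.18e-11), fatty acid synthesis (4.97e-05), SF3b and U2 (1.12e-06) and other spliceosome genes (3.51e-08), each given as adjusted p. With an estimated correlation the adjusted p was 0.0469 for HIF targets, 0.0366 for glycolysis and 0.0144 for both splicing lists. The other calls were lost with an estimated correlation (adjusted p = 0.0683 for replication, 0.210 for mitosis, 0.237 for cholesterol and 0.208 for fatty acids). With the block and an estimated correlation none of these lists was called (adjusted p from 0.0714 to 0.182). The interferon list, with a median of -0.61, was called only with the block (adjusted p = 0.000102 against 0.0785, and 0.561 with the block and an estimated correlation). KP 616 and KP 625 did not correlate with themselves across oxygen levels (-0.071 and -0.006), so the values with a block rest on a pairing that the data bear out for 1 of 3 KP lines. Leaving out any 1 of the 6 libraries moved the count by over 1.5 times, to between 114 genes (without hypoxic KP 625) and 476 (without normoxic KP 571).

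In KPC, hypoxia lowered replication and splicing genes, and few HIF targets passed the threshold in the fit without a block. The HIF target score nevertheless rose in each line, by 0.775 (571), 0.695 (616) and 0.748 (625). The counts of list members that follow are from the fit without a block. HIF targets rose in 1 of 57 members, the histone demethylase gene Kdm3a at 1.22 ± 0.31 (SE, adjusted p = 0.0421), with 9 over the list alone and a median of 0.71. Replication genes fell in 8 of 28 members (23 over the list alone, median -1.07), such as Chaf1b (-1.24), Mcm7 (-1.13), Gins2 (-1.13) and Mcm2 (-1.42). Among the largest single falls, Cad, which starts pyrimidine synthesis, changed by -1.64 ± 0.36 (adjusted p = 0.0279), Dkc1, the pseudouridine synthase dyskerin, by -1.56 ± 0.34 (adjusted p = 0.0273), Grwd1 by -1.58 and Klhdc7a by -2.01. Among the largest rises were Hmox1, heme oxygenase, at 1.45 ± 0.38 (adjusted p = 0.0485), and Sqstm1, the autophagy receptor p62, at 1.36 ± 0.33 (adjusted p = 0.0383). Nqo1, an NRF2 target, rose by 2.62 and Gsr, glutathione reductase, fell by 0.90. Splicing genes fell in 3 of 17 members of the SF3b and U2 list (7 over the list alone) and in 6 of 32 others (13 over the list alone), with Prpf31 at -1.29 and U2af1 at -0.61.

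In limma, 147 genes rose and 341 fell in KPC, 488 in all, of which 30.1% were higher. Centring each library on its median turned this share to 60%, because it moved the median change of all genes to 0.15 in KPC, 0.11 in KPS and 0.15 in KPCS. Relative to those shifts, the centred medians of the SF3b and U2 list (-0.22, -0.20 and -0.28) and of the other spliceosome genes (-0.24, -0.40 and -0.30) stayed below 0. With the line as a block 2852 genes changed (1359 higher, 1493 lower). The lists of HIF targets (adjusted p = 3.59e-10), replication (1.59e-16), SF3b and U2 (1.01e-06) and other spliceosome genes (3.94e-08) were called. Those of HIF targets and replication were lost with an estimated correlation (adjusted p = 0.490 and 0.336), and both splicing lists had adjusted p = 0.0118. With the block and an estimated correlation the splicing lists had adjusted p = 0.361 and 0.177. The list of MAPK output genes, median 0.31, was called with the block only (adjusted p = 0.00575 against 0.0805, and 0.501 with an estimated correlation as well). Without hypoxic KPC 625 the count was 4 and without normoxic KPC 571 it was 10, while without hypoxic KPC 571 it was 449.

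In KPS, replication genes again formed the largest group of falls. They fell in 21 of 28 members (27 over the list alone, median -1.71), with Mcm6 at -2.43 ± 0.41 (SE, adjusted p = 0.00654), Ccne1, cyclin E, at -2.02 ± 0.30 (adjusted p = 0.00349), and Tyms, thymidylate synthase, at -2.15 ± 0.41 (adjusted p = 0.0107). Mitotic genes fell in 7 of 24 members, such as Kif20a (-1.94) and Cdk1 (-1.69), with a median of -1.45, and of -0.68 with the line as a block. The mean of mitotic genes was 9.09 in the unpaired hypoxic library of KPS 530, against 11.61 and 10.63 in hypoxic KPS 520 and KPS 528. Enzymes of the citric acid cycle fell in 6 of 17, such as Dlat (-0.67) and Idh3a (-1.23). HIF targets rose in 16 of 57 members (40 over the list alone, median 1.31), such as P4ha1 (1.73), Kdm4b (1.41) and Egln1 (1.42), the last a prolyl hydroxylase that marks HIF for degradation. Among other rises were Mt1, a metallothionein, at 1.92, and Relb and Nfkbia of the NF-κB pathway at 1.26 and 1.62. Other spliceosome genes fell in 8 of 32 members (16 over the list alone), with Snrpd1 at -0.99 and Eftud2 at -1.17.

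In limma 341 genes rose and 733 fell in KPS, 1074 in all, of which 31.8% were higher, and 42.9% after median centring. With the line as a block, which drops the unpaired hypoxic library of KPS 530, 2408 genes changed (1197 higher, 1211 lower), 994 of them shared with the fit without it. The lists of replication (adjusted p = 2.33e-21), HIF targets (7.83e-17), mitosis (1.77e-13), citric acid cycle enzymes (2.54e-07) and other spliceosome genes (7.62e-07) were called. With an estimated correlation only the last of these was called (adjusted p = 0.0392), and the others had adjusted p from 0.137 to 0.312. With the block and an estimated correlation the spliceosome list had adjusted p = 0.224. With the block, cholesterol synthesis genes were called as higher (adjusted p = 8.74e-05 against 0.447), with a median of 0.41 against -0.23 in the fit that includes hypoxic KPS 530. Called as higher with the block only were also ATF4 targets (median 0.36, 0.00276 against 0.765), p53 targets (0.36, 0.000681 against 0.276) and MAPK output genes (0.48, 0.00662 against 0.128). With the block and an estimated correlation these 4 lists had adjusted p from 0.406 to 0.493. With only 2 normoxic libraries, leaving out KPS 520 or KPS 528 in normoxia left 8 or 15 genes, and leaving out hypoxic KPS 530 left 350.

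In KPCS, the HIF response, glycolysis and autophagy genes rose. HIF targets rose in 41 of 57 members (44 over the list alone, median 1.41), with Ak4, a mitochondrial adenylate kinase, at 3.38 ± 0.58 (SE, adjusted p = 0.00750), Bnip3 at 2.84 ± 0.58 (adjusted p = 0.0134), P4ha1 at 2.26 ± 0.36 (adjusted p = 0.00446) and Aldoc at 2.21 ± 0.37 (adjusted p = 0.00623), although Ak4 is not a member of the list. Glycolytic genes rose in 17 of 20 members, such as Aldoa (1.83), Tpi1 (1.26) and Pgk1 (2.02). Autophagy and lysosome genes rose in 6 of 20, such as Sqstm1 (1.69), Bnip3l (1.40) and Ctsd (0.98). ATF4 targets rose in 3 of 26 members (4 over the list alone, median 0.32, list adjusted p = 0.0388, and 0.781 with an estimated correlation), among them Ddit3, which encodes CHOP, by 3.10 and Atf3 by 2.56. Hmox1, an NRF2 target, rose by 2.02. Replication genes fell in 10 of 28 members (25 over the list alone, median -0.99), and the largest single falls included Ranbp1 (-1.90), of nuclear transport, and Rrs1 (-1.71) and Rrp12 (-1.92), of ribosome assembly. SF3b and U2 genes fell in 7 of 17 members (10 over the list alone), such as Sf3b4 (-1.19) and Sf3a3 (-0.80), and other spliceosome genes fell in 8 of 32 and rose in 1. Mitochondrially encoded genes fell in 4 of 11, such as ND1 (-1.05) and CYTB (-1.22), although the mean of the list went from 12.68 to 13.06 in KPCS 528, against 13.23 to 12.50 in KPCS 520 and 13.36 to 12.90 in KPCS 530.

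In limma 550 genes rose and 672 fell in KPCS, 1222 in all, of which 45% were higher, and 69.2% after median centring. With the line as a block 3877 genes changed (1918 higher, 1959 lower). The lists of HIF targets (adjusted p = 1.18e-26), glycolysis (8.90e-15), replication (6.26e-13), autophagy (9.88e-06), SF3b and U2 (9.02e-07) and other spliceosome genes (1.14e-06) were called. With an estimated correlation both splicing lists were called (adjusted p = 0.0209), and the others were not (0.147, 0.147, 0.262 and 0.1499). With the block and an estimated correlation the splicing lists had adjusted p = 0.370 and 0.334. MAPK output genes, median 0.33, were called with the block only (adjusted p = 0.00858 against 0.0507, and 0.508 with an estimated correlation as well). The count was 169 without hypoxic KPCS 530, 140 without normoxic KPCS 530, 230 without hypoxic KPCS 520, 392 without normoxic KPCS 528 and 2910 without hypoxic KPCS 528.

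Across the genotypes, which share no libraries, 17 genes rose and 124 fell in all 4, and none rose in 1 genotype and fell in another. Kdm3a, Ctns, Atp6v0b and Tom1l2 were among the 17, and U2af1, Sf3b3, Snrpd1, Mcm2, Mcm6, Cycs and Cad were among the 124. Of the falls, 201 genes were shared by KP and KPCS, against 16.8 for independent lists, and 281 by KPC and KPCS, against 13.9. Of the rises, 129 were shared by KP and KPCS, against 11.3, and 19 by KP and KPC, against 3.0. All 4 comparisons used the same spread per gene from 1 fit, so the figures for independent lists are a rough reference and not a test. Log2 changes correlated across genes between 0.551 (KP and KPC) and 0.857 (KPC and KPCS), with genes not independent replicates.

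The size of the HIF response was compared between genotypes as the change of the HIF target score per line. The score rose by 1.63 ± 0.11 in KP, 0.74 ± 0.04 in KPC and 1.43 ± 0.93 in KPCS (SD, n = 3 lines each), and by 1.197 ± 0.061 in KPS (SD, n = 2 lines). The KPC lines gave 0.69, 0.75 and 0.78, all below the lowest KP line at 1.502. The difference of KPC to KP was -0.89, with p = 0.1 in a two-sided exact permutation test, the smallest p that 20 assignments allow (adjusted p = 0.2 over 4 comparisons). KPS differed from KP by -0.43 (exact p = 0.1, the smallest of 10 assignments, adjusted p = 0.2). KPCS exceeded KPC by 0.69 (exact p = 0.4, adjusted p = 0.533) and KPS by 0.23 (exact p = 0.9, adjusted p = 0.9). The KPCS lines gave 0.66, 1.16 and 2.47, and without KPCS 530, the highest, the difference to KPC was 0.17 and that to KPS was -0.29. Levels differed most in normoxia, where the score was 10.85 ± 0.20 in KP and 11.76 ± 0.20 in KPC (SD, n = 3). In hypoxia it was 12.47 ± 0.11 and 12.50 ± 0.18.

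**Figure D3:**
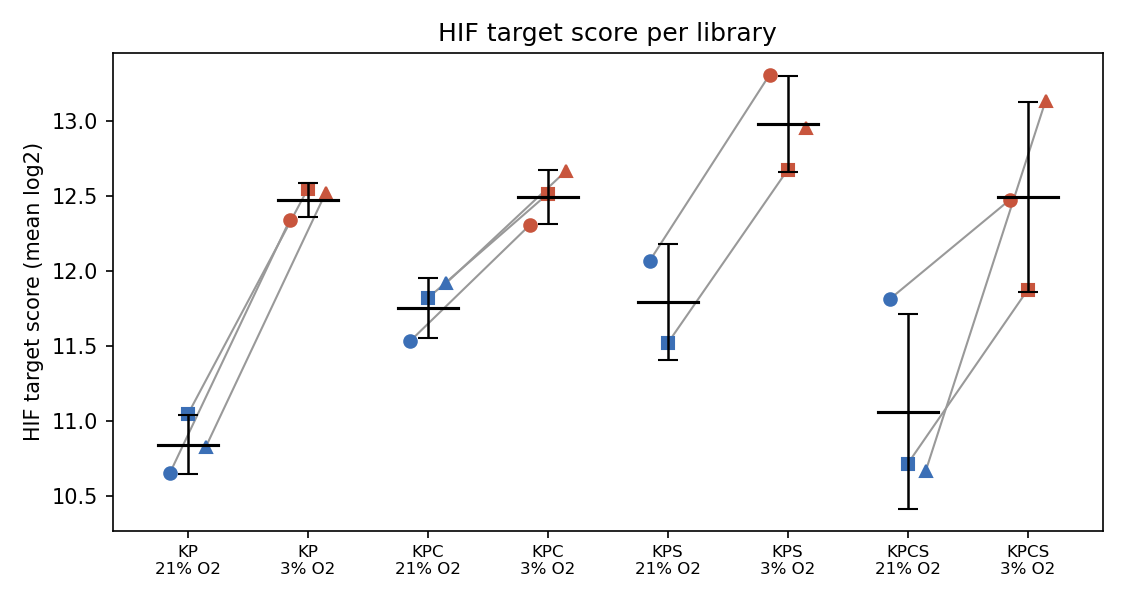
HIF target score, the mean log2 value of 57 HIF targets (vertical axis), per library by genotype and oxygen level (horizontal axis). Grey lines join the normoxic and hypoxic library of an organoid line, bars give group means with the SD, and circle, square and triangle mark the 3 organoid numbers of a genotype in ascending order. KPC lines changed by 0.69 to 0.78 and KP lines by 1.502 to 1.693.

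Tested gene by gene, the hypoxia response of KPCS differed from that of KPC in 0 genes (limma, 76 genes at an unadjusted p under 0.05), and 0 with the line as a block. That of KPC differed from that of KP in 0 genes (914 at an unadjusted p under 0.05), and in 35 with the block (15 higher, 20 lower). With hypoxic KP 616 and KP 625 exchanged in the block it was 108 genes. As a list, HIF targets differed in response by a median of 0.66 for KPCS against KPC (adjusted p = 2.41e-29) and of -0.81 for KPC against KP (adjusted p = 2.38e-17), with 0 of 57 passing in either and 4 lower over the list alone in the second. These calls were lost with an estimated correlation (adjusted p = 0.225 and 0.533). The cholesterol synthesis list had a median of -0.89 for KPC against KP (adjusted p = 2.14e-11, and 0.656 with an estimated correlation), with all 24 differences below 0 and 0 passing, also over the list alone. With the block and an estimated correlation this list and that of fatty acid synthesis, median -0.74, both had adjusted p = 0.0360, and 0.0783 with hypoxic KP 616 and KP 625 exchanged in the block. ATF4 targets differed the other way, by 0.56 (adjusted p = 0.00386, and 0.842 with an estimated correlation). With the block alone, lists of interferon response (0.00517 against 0.235), mesenchymal genes (0.0224 against 0.0732), basal-like tumour genes (0.0153 against 0.313) and p53 targets (0.0321 against 0.318) were also called for KPC against KP, and metal-handling genes (0.0460 against 0.203) for KPCS against KPC, as adjusted p. None of these 5 calls remained with the block and an estimated correlation (adjusted p from 0.421 to 0.748).

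Lines with and without Ptf1a-Cre were first compared as KPC against KP in normoxia. KPC organoids had higher HIF targets and glycolytic genes at 21% oxygen. HIF targets rose in 10 of 57 members (33 higher and 1 lower over the list alone, median 0.96), such as Ankrd37 (2.23 ± 0.48, SE, adjusted p = 0.0240), Pfkp (2.19 ± 0.43, adjusted p = 0.0176) and Aldoc (1.80 ± 0.37, adjusted p = 0.0198), and Bnip3 was higher by 2.42. Glycolytic genes were higher in 8 of 20 members and lower in 1. Krt19, a ductal keratin, was higher by 1.92 ± 0.30 (adjusted p = 0.00415), Tjp1, which encodes the tight junction protein ZO-1, by 0.88, and Atp2c2 by 2.96. Gc, the vitamin D binding protein gene, was lower at -5.53 ± 1.12 (adjusted p = 0.0192), Gxylt2 at -4.91, the chemokine gene Ccl2 at -3.54 and Spp1, osteopontin, at -2.97. Of 22 genes of NF-κB inflammation, 1 was lower (2 over the list alone), with a median of -0.52 (list adjusted p = 0.00218, and 0.385 with an estimated correlation). Of 17 mesenchymal genes, 0 passed (0 over the list alone), although 16 were below 0 with a median of -1.10, such as Vim at -3.88 ± 1.49 (adjusted p = 0.198). The mean of this list was 7.975 in KPC 616, against 6.22 and 6.63 in KPC 571 and KPC 625 and 8.13 to 8.43 in KP, and Vim stood at 11.29 in KPC 616, against 6.35 and 7.17. ATF4 targets passed in 0 of 26 members and in 9 over the list alone, with a median of 0.87.

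In limma 129 genes were higher and 159 lower in normoxic KPC than in KP, 288 in all. HIF targets (adjusted p = 1.36e-17), glycolysis (1.40e-12), ATF4 targets (3.77e-07), epithelial junction genes (3.69e-05, median 0.60) and mesenchymal genes (3.09e-04) were called as lists. All of these were lost with an estimated correlation (adjusted p = 0.345, 0.345, 0.385, 0.345 and 0.345). The count was 34 without KPC 571, 46 without KP 616, 50 without KPC 625 and 72 without KP 571. KPS, which lacks Cre, also lay nearer to KPC than to KP on these lists in normoxia. List means in KP, KPC and KPS (n = 3, 3 and 2) were 10.845, 11.758 and 11.795 for HIF targets and 12.129, 13.168 and 13.106 for glycolysis. They were 10.800, 11.738 and 11.496 for ATF4 targets, 11.147, 11.775 and 11.698 for junction genes, and 8.243, 6.942 and 7.137 for mesenchymal genes. These differences from KP were therefore not particular to lines with Cre.

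In hypoxia, KPC and KP differed in 1761 genes, and HIF targets were no longer among the lists that differed (1 of 57 lower, Pfkl at -0.81, median 0.10, which turned to -0.002 after quantile normalization, adjusted p = 0.940). Of 26 ATF4 targets 13 were higher (20 over the list alone, median 1.54), among them Asns, asparagine synthetase, at 2.65 ± 0.53 (SE, adjusted p = 0.00788), Slc7a5 and Slc3a2, subunits of an amino acid transporter, at 1.83 and 1.79, Ddit3 at 2.83 and Trib3 at 2.96. MAPK output genes were higher in 8 of 26 members (10 over the list alone, median 0.77), with the EGF receptor ligand genes Areg at 3.31 ± 0.43 (adjusted p = 0.00126) and Ereg at 2.49 ± 0.47 (adjusted p = 0.00652), and Dusp5 at 1.61. Among the largest falls were the complement gene C3 at -3.20, the lipocalin gene Lcn2 at -2.84, Saa3, serum amyloid A3, at -4.28 and Lbp, which binds bacterial lipopolysaccharide, at -3.32, and Gxylt2 was again lower (-4.01 ± 0.89, adjusted p = 0.0116). Cd14, an immune marker that epithelia can also express, was lower at -1.999, and Cd68 was higher by 1.70. Mitotic genes were higher in 2 of 24 members (7 over the list alone, median 0.97).

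In limma 904 genes were higher and 857 lower. ATF4 targets (adjusted p = 2.12e-09), MAPK output genes (1.31e-04) and mitotic genes (1.79e-06) were called as lists, and were lost with an estimated correlation (adjusted p = 0.841, 0.736 and 0.960). The count fell to 286 without KPC 625 and to between 553 and 732 without KPC 571 or any single KP library, and it was 1792 without KPC 616.

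The same contrast in lines with floxed Sf3b1 was KPCS against KPS. In normoxia 5 genes were lower and 0 higher in KPCS in limma, with 1867 genes at an unadjusted p under 0.05. Znrf2, a ubiquitin ligase gene, was lower at -0.86 ± 0.13 (SE, adjusted p = 0.0227). The others, named after their values were seen, were Gstm3, with a low mean of 2.521 over all libraries, Slc6a19, Chst9 and Gimap8. In hypoxia Slc20a1, a phosphate transporter gene, was higher by 1.63 ± 0.26 (adjusted p = 0.0271) and 5 genes were lower, Arid2, a chromatin remodelling subunit, at -0.75 ± 0.13 (adjusted p = 0.0408) and, named after their values were seen, Gm853, Acmsd, 4631405J19Rik and Gm44164. No member of the HIF target list passed in normoxia (1 lower over the list alone), although its median was -0.68 (list adjusted p = 6.59e-11, and 0.716 with an estimated correlation). The score of KPCS 520 (11.814) lay within the range of KPS (11.521 to 12.070), and only KPCS 528 (10.717) and KPCS 530 (10.667) lay below it. Replication genes in hypoxia passed in 0 of 28 members and in 11 over the list alone, all higher, with a median of 0.79 (list adjusted p = 3.53e-13, and 0.328 with an estimated correlation), such as Ccne1 at 1.49 ± 0.27 (adjusted p = 0.0507). The spread between lines was wide, with list means of 9.107 ± 0.563 in hypoxic KPS and 9.882 ± 0.524 in hypoxic KPCS (SD, n = 3 each). MAPK output genes had medians of 0.37 in normoxia and 0.52 in hypoxia (list adjusted p = 3.83e-04 and 2.13e-05, and 0.716 and 0.302 with an estimated correlation), with 0 of 26 passing and 7 and 8 higher over the list alone. Quantile normalization gave 12.5% higher calls in normoxia against 0.0%, and 42.9% in hypoxia against 16.7%. Median centring left 0 genes in hypoxia. With the organoid number as a block, 276 genes changed in hypoxia (154 higher, 122 lower), Slc20a1 and Arid2 among them, and Ccne1 passed with adjusted p = 0.0135. The count in hypoxia was 401 without KPCS 530, 34 without KPS 520, 14 without KPS 528 and 0 without KPCS 520 or KPCS 528. In normoxia it was 13 without KPCS 528, 2 without KPS 520, 1 without KPCS 530 and 0 without KPS 528.

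The floxed allele was compared on a Cre-positive background in KPCS against KPC. In normoxia 32 genes were higher and 33 lower in KPCS, and in hypoxia 18 were higher and 11 lower (limma). Eif3j1, a translation initiation factor subunit, was higher by 1.60 ± 0.16 in normoxia (SE, adjusted p = 2.82e-05) and 1.23 ± 0.16 in hypoxia (adjusted p = 7.63e-04), and Apobec3, an antiviral cytidine deaminase, by 1.38 ± 0.18 and 1.87 ± 0.18 (adjusted p = 0.00138 and 4.92e-05). Vars, valyl-tRNA synthetase, was higher by 0.93 and 1.18. Smn1, needed for the assembly of splicing particles, was higher by 0.76 in normoxia, and Prmt5, an arginine methyltransferase, by 0.73 in hypoxia. Bst1 (-1.09), Wfdc2 (-0.79) and Pddc1 (-0.57) were lower in normoxia. The 65 and 29 genes are set against those between KPS and KP in the closing section.

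Genes of the SF3b complex and U2 particle moved together between KPCS and KPC, apart from Sf3b1 itself. In normoxia 16 of 17 lay above 0, with a median of 0.30, while 0 passed over all genes and 9 were higher and 1 lower over the list alone. Sf3b4 stood at 0.95 ± 0.24 (SE, adjusted p = 0.117), Sf3a2 at 1.03 ± 0.29 (adjusted p = 0.135) and Sf3b3 at 0.40 ± 0.11 (adjusted p = 0.128), and Sf3b1 stood at -0.62. In hypoxia the median was 0.29, with 16 of 17 above 0, 0 passing and 2 over the list alone. The list was called at both oxygen levels (adjusted p = 1.93e-06 and 4.12e-06), also with an estimated correlation (adjusted p = 0.0234 and 0.0197). Other spliceosome genes had medians of 0.20 and 0.21 (adjusted p = 1.17e-04 and 4.12e-06, and 0.0822 and 0.0197 with an estimated correlation), with 0 of 32 passing and 8 and 0 over the list alone.

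Among other lists in KPCS against KPC, immune markers were higher in hypoxic KPCS, with a median of 0.64 over 7 genes (adjusted p = 0.00200, and 0.0197 with an estimated correlation). None of the 7 passed alone, and 1 did over the list alone, and Csf1r, a macrophage growth factor receptor, stood at 1.90 ± 0.41 (adjusted p = 0.0739). In KPS against KP the median of this list was 0.66 in normoxia (adjusted p = 0.0485, and 0.420 with an estimated correlation) and 0.71 in hypoxia (adjusted p = 0.570). Interferon response genes lay lower, with medians of -0.79 and -0.75 (adjusted p = 0.00174 and 7.02e-04, and 0.949 and 0.939 with an estimated correlation), with 0 of 28 passing in either, also over the list alone. Their means in KPC 616 were 9.09 in normoxia and 8.87 in hypoxia, while KPC 571 (7.63 and 7.56) and KPC 625 (6.74 and 6.69) lay near KPCS (7.09 ± 0.44 and 6.97 ± 0.32, SD, n = 3). HIF targets had a median of -0.65 in normoxia (adjusted p = 1.91e-11, and 0.556 with an estimated correlation), with 0 of 57 passing and 5 lower over the list alone. Their score in KPCS 520, 11.81, lay within the range of KPC (11.53 to 11.92), and only KPCS 528 (10.72) and KPCS 530 (10.67) lay below it. The count of genes in normoxia was 19 without KPC 571 or KPC 616, 23 without KPC 625, 27 without KPCS 530 and 102 without KPCS 528, and in hypoxia it was 61 without KPCS 530.

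Without Cre, KPS was compared with KP. In normoxia 96 genes were higher and 50 lower in KPS, and in hypoxia 124 were higher and 115 lower (limma). Genes of chromosome 15 were raised in both normoxic KPS libraries, by medians of 0.33 (520) and 0.43 (528), as described in the closing section. In hypoxia the shifts were 0.36 (520), 0.38 (528) and 0.025 (530). This shift was not separated from the genotype. Cyp2s1 was higher by 3.53 ± 0.55 in normoxia (SE, adjusted p = 0.00658), Atp10b, a lipid flippase gene, by 3.45 ± 0.64 (adjusted p = 0.0149), and Pdk1, which restrains entry of pyruvate into the citric acid cycle, by 1.72 ± 0.34 (adjusted p = 0.0208). Filip1l (-1.25), the chemokine gene Cxcl16 (-1.17) and Socs5 (-0.97) were lower. In hypoxia Atp10b (2.54), Areg (1.76) and Scel (1.74) were higher, and Cyp1b1 (-3.43 ± 0.66, adjusted p = 0.0244), Cd14 (-1.68), Cxcl5 (-1.59) and Sod2 (-1.09), mitochondrial superoxide dismutase, were lower. Csf1r was higher at both oxygen levels, by 2.72 ± 0.46 and 2.32 ± 0.41 (adjusted p = 0.0102 and 0.0138). HIF targets passed in 1 of 57 members in normoxia (27 over the list alone), with a median of 0.99 (list adjusted p = 5.27e-19, and 0.441 with an estimated correlation). Neither splicing list was called. Leaving out KPS 520 or KPS 528 in normoxia left 7 or 9 genes, and leaving out any normoxic KP library left 47 to 56. In hypoxia the count was 1213 without KPS 530, 25 without KPS 520 and 29 to 41 without any single KP library.

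The Cre effect with floxed Sf3b1 was tested against that without it. Each oxygen level gave 4 genes, all lower (limma, 1854 and 2126 genes at an unadjusted p under 0.05). In normoxia Pdk1 differed by -2.90 ± 0.46 (SE, adjusted p = 0.0341). HIF targets as a list differed by a median of -1.58 in normoxia, with 1 of 57 passing and 38 over the list alone (adjusted p = 4.65e-29, and 0.154 with an estimated correlation). In hypoxia the median was -0.52, with 0 passing (adjusted p = 0.00293, and 0.873 with an estimated correlation). ATF4 targets differed in hypoxia by a median of -1.12, with 0 of 26 passing, also over the list alone (adjusted p = 1.31e-05, and 0.873 with an estimated correlation), such as Slc7a5 at -1.55 ± 0.55 (adjusted p = 0.279). Sf3b1 differed by -0.87 ± 0.32 in hypoxia (adjusted p = 0.289). Quantile normalization gave 33 genes in normoxia, of which 18.2% were higher against 0.0%. Without KPCS 520 the normoxic count was 58, and in hypoxia it was 798 without KPCS 530 and 63 without KPS 530, while most other libraries left out gave 1.

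**Figure D4:**
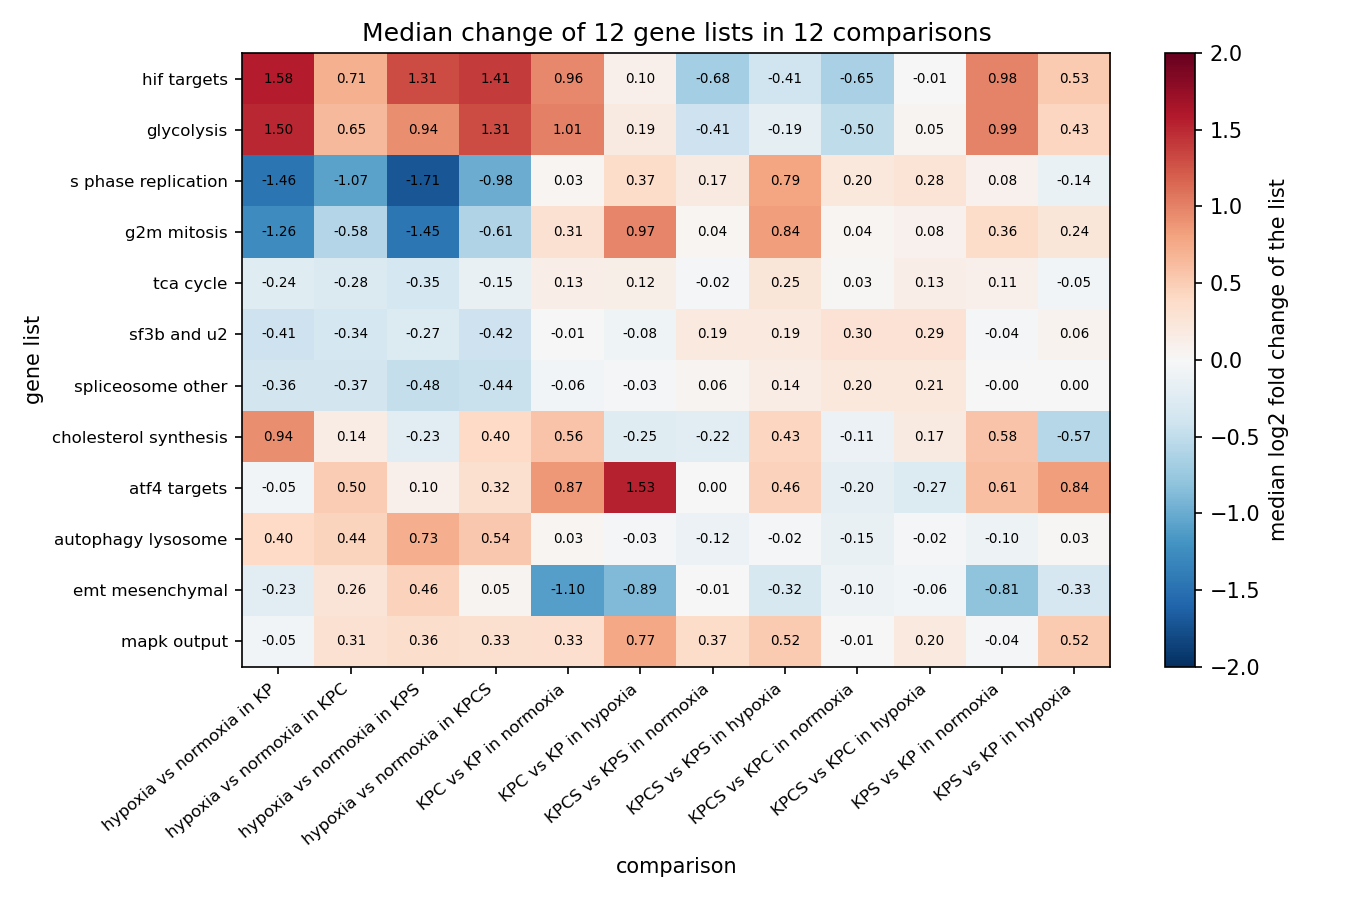
Median log2 difference (colour scale, from -1.71 to 1.58) of 12 gene lists (rows) in 12 comparisons of groups (columns). HIF targets have medians of 1.58, 0.71, 1.31 and 1.41 in hypoxia against normoxia in KP, KPC, KPS and KPCS, and replication genes have -1.46, -1.07, -1.71 and -0.99.

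The authors' deposited table covered 10 of these comparisons, without those of KPCS to KPC and KPS to KP and the 2 differences of hypoxia responses. Its log2 fold changes correlated with those of the limma fit across genes at 0.911 to 0.960, and no gene called in both went in opposite directions. At an adjusted p under 0.01 it listed 245 higher and 351 lower genes for hypoxia in KP, 575 of them also called here. For KPCS against KPS in normoxia the authors' deposited table listed 121 higher and 40 lower genes, against 0 and 5 here. The test behind it is not given in the sources used here.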

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

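All tests of explanations in this part were chosen after the results they concern were seen. The groups of 2 or 3 libraries are too small for a test of single outlying libraries. What drew attention here was a difference between 2 groups' effects under the same contrast, by a test of that difference.

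The HIF target list was called in all 4 such tests. Its median difference was 0.660 for the hypoxia response of KPCS against that of KPC, and -0.810 for that of KPC against that of KP. For the Cre effect with floxed Sf3b1 against that without, it was -1.577 in normoxia and -0.519 in hypoxia. None of these calls remained with an estimated correlation (adjusted p from 0.154 to 0.873).

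Among single genes, 4 differed between the Cre effects in normoxia: Gcnt4 (-3.349, adjusted p = 0.00416), Gm16531 (-1.851, adjusted p = 0.0156), Pdk1 (-2.900, adjusted p = 0.0341) and Gstm3 (-1.350, adjusted p = 0.0379). In hypoxia these were Gcnt4 (-3.085, adjusted p = 0.00576), Trim69 (-1.291, adjusted p = 0.0357), Gm16531 (-1.587, adjusted p = 0.0357) and Gk5 (-1.084, adjusted p = 0.0484). Apart from Pdk1, these genes were chosen after their values were seen. Gm16531, Gstm3 and Trim69 had low means over all libraries, 2.910, 2.521 and 3.183, against a median of gene means of 9.039. With the low-expression filter 2 genes were called in normoxia and 1 in hypoxia.

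The smaller HIF response of KPC than of KP was set against 3 explanations. For the authors' scaling, quantile normalization of the deposited values left the difference of changes at -0.960. Differences in distribution that remained between the libraries thus do not account for it. The authors' own normalization could not be undone without counts, so its part is left open. For a weaker response to hypoxia across genes, genes outside the list that were called in KPS or KPCS were used. The ratio of their median changes, KPC to KP, was 0.917 for rises and 1.040 for falls called in KPS, and 1.610 and 1.374 for those called in KPCS. Genes called in KPCS favour KPC, whose changes correlated with those of KPCS at 0.857, against 0.564 for KP. Genes called in KP were not used. Means of mitotic genes went from 11.533 to 10.261 in KP and from 11.833 to 11.206 in KPC under hypoxia. A weaker response of KPC beyond the HIF targets is therefore not excluded. A higher starting level could not be tested separately: the score of KPC exceeded that of KP by 0.913 in normoxia and by 0.025 in hypoxia. The difference of changes is made of these same values, so they restate it. The normoxic score was 11.795 ± 0.388 in KPS, which lacks Cre (SD, n = 2), and 11.066 ± 0.648 in KPCS, which carries it (SD, n = 3). The group means thus did not follow Cre across the genotypes. The data do not separate an effect of Cre on the normoxic level from other differences between these lines, and the exact test of the difference of changes had p = 0.1.

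The genes called between KPCS and KPC were weighed against a background difference between lines with and without the floxed allele, which KPS against KP would share. Of the 65 genes in normoxia, 56 (86.2%) had the same sign in KPS against KP, and of the 29 in hypoxia 26 (89.7%), against 49.3% and 53% of all other genes. Of these, 20 and 16 were called in the same direction in both, against 0.6 and 0.4 for independent lists, and 34 and 18 were at least 0.5 times as large, with medians of 0.588 against 1.335 and 0.935 against 1.692. Both comparisons used the same spread per gene from 1 fit, so the figures for independent lists are a rough reference. Such a background difference therefore remains a candidate for the direction of these genes, while the remainder of their size is left open. The SF3b and U2 list had a median in KPS against KP of -0.044 in normoxia (KPS n = 2) and 0.063 in hypoxia (0.112 after median centring). In KPCS against KPC its medians were 0.296 and 0.294. These values argue against a background difference shared with KPS as the whole cause for this list. They were compared without an error, and cannot rule out a difference particular to the KPCS or KPC lines.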

How the results depend on the processing

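The settings that leave out number 530 or exchange hypoxic KP 616 and KP 625 were chosen after seeing the data. No called value of a named gene reversed under any setting, and the uncalled HIF score difference of KPCS to KPS changed sign when number 530 was left out. Counts of genes are given in the order of the comparisons named, and the cause of a change was not tested except where a setting tests fewer genes or libraries by construction.

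With quantile normalization KPCS against KPS in normoxia gave 8 genes, the difference of Cre effects gave 33 in normoxia and 1 in hypoxia, and the HIF score difference of KPS to KP was -0.606. Median centring left 0 genes for KPCS against KPS in hypoxia. The low-expression filter gave 186 for KPC against KP in normoxia, and in normoxia and hypoxia 1 and 0 for KPCS against KPS, 22 and 13 for KPCS against KPC, 50 and 118 for KPS against KP, and 2 and 1 for the difference of Cre effects. Without trend and robust fit, KPCS against KPS in hypoxia gave 15 and the difference of Cre effects in normoxia 10. The fold minimum, which can only remove genes, left 344, 162, 524 and 454 for hypoxia in KP, KPC, KPS and KPCS, 880 for KPC against KP in hypoxia, 3 and 3 for KPCS against KPS, 42 for KPCS against KPC in normoxia and 126 for KPS against KP in hypoxia. The HIF score difference of KPC to KP was -1.215 as the median of members and -0.970 over members above the median.

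Fitted on the compared groups only, where the spread comes from those groups alone, hypoxia gave 2305, 899, 0 and 0 genes in KP, KPC, KPS and KPCS. In normoxia and hypoxia KPC against KP gave 697 and 2833, KPCS against KPS 0 and 0, KPCS against KPC 1 and 0, KPS against KP 482 and 0, and the difference of Cre effects 10 and 0. The response of KPC against that of KP gave 34.

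With the line as a block, hypoxia gave 2772, 2852, 2408 and 3877 genes, and the response of KPC against that of KP 35. With hypoxic KP 616 and KP 625 exchanged in the block, hypoxia in KP gave 3106 and that response 108, and the interferon list in KP had adjusted p = 1.91e-06, and 0.278 with an estimated correlation. What a number shared across Cre status stands for is not given in the labels. With its block KPC against KP gave 1343 and 3806, KPCS against KPS 86 and 276, and the difference of Cre effects 116 and 166. Correlations of deviations with the same number ran from -0.185 to 0.516, all above 0.1 only for KPCS against KPS in hypoxia, and 16 of 22 libraries correlated best with their own number. This block called KPCS against KPS in normoxia for replication (0.000827), mitosis (0.0300) and epithelial junction genes (0.0431), and the difference of Cre effects for replication in normoxia (0.0330) and NF-κB genes in hypoxia (0.0462), none of them with an estimated correlation as well (adjusted p from 0.7905 to 0.823). It lost oxidative phosphorylation (0.0573), endocrine (0.0724) and gastric genes (0.0529) for KPC against KP in normoxia and NRF2 targets (0.0933) for the difference of Cre effects in normoxia. The block changed no other list call at the preset correlation. No paired analysis was possible because KPCS and KPC, and KPS and KP, share no numbers.

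Without number 530, hypoxia in KPCS gave 60 genes, KPCS against KPS 21 and 66, KPCS against KPC 117 and 178, KPS against KP 559 and 2198, and the difference of Cre effects 36 and 1045. With the block as well, hypoxia gave 4382 in KPS and 1861 in KPCS, KPCS against KPS 235 and 782, and the difference of Cre effects 402 and 3115.

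Leaving out 1 library at a time gave 114 to 476 genes for hypoxia in KP, 4 to 449 in KPC, 8 to 1422 in KPS and 140 to 2910 in KPCS. In normoxia and hypoxia it gave 34 to 360 and 286 to 1792 for KPC against KP, 0 to 13 and 0 to 401 for KPCS against KPS, 19 to 102 and 21 to 61 for KPCS against KPC, 7 to 56 and 25 to 1213 for KPS against KP, and 1 to 58 and 1 to 798 for the difference of Cre effects. Both differences of hypoxia responses stayed at 0. The HIF score difference ran from 0.170 to 1.074 for KPCS to KPC, -0.951 to -0.855 for KPC to KP, -0.288 to 0.616 for KPCS to KPS and -0.493 to -0.387 for KPS to KP. Where this left 1 normoxic KPS library, that library is assumed to vary like the other groups.

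Of values for the genes named as largest rises or falls, 132 of 147 kept their call under the low-expression filter and 135 under median centring. The number was 142 under quantile normalization, 143 without trend and robust fit, and 69 in the compared groups only. Under leave-one-out it was 349 of 854. All others were weaker in the same direction, which the choice of genes fixed for leave-one-out in comparisons of 2 groups. Of 512 list tests 150 were called at the preset correlation and 13 of those with an estimated correlation. Pseudocounts and count-based tools were not run, since the values were already on a log2 scale without counts. Depth is unknown, so its limits were not analysed here.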

Other observations

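All tests of explanations and all splits in this part were chosen after the results they concern were seen.

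Shifts of expression over whole chromosomes appeared in 7 pairs of a line and a chromosome, on chromosomes 3, 15 and 19, in both libraries of the line. Chromosome 15 was raised in KPS 520 (0.33 in normoxia and 0.36 in hypoxia), KPS 528 (0.43 and 0.38) and KPCS 520 (0.41 and 0.34), chromosome 19 in KPC 571 (0.41 and 0.34) and KPS 528 (0.40 and 0.37), and chromosome 3 in KPC 616 (0.26 and 0.26), as median log2 differences, against a largest shift of 0.158 in any KP library. The smallest median of the genes on either side of the chromosome's middle was 0.315, 0.375 and 0.330 for chromosome 15 in these 3 lines, 0.243 and 0.323 for chromosome 19 and 0.252 for chromosome 3, so a gain of the whole chromosome in part of the cells is a candidate explanation, with 0.585 for 3 copies against 2. In KPCS 530 1 side of chromosome 19 was at 0.075 in normoxia, which leaves a gain open. No copy-number data were analysed here, and no other biological explanation was tested. Both normoxic KPS libraries carried the shift of chromosome 15, so KPS against KP in normoxia cannot be told apart from it. The share of called genes on these chromosomes was not analysed here.

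Libraries of organoid number 530 carried Xist at 13.52 to 14.68, and all other libraries at 3.81 to 6.62. The genes in this paragraph were chosen after their values were seen. The Y-linked gene Ddx3y lay at 6.13 to 6.19 in number 530, at 8.88 in normoxia and 9.08 in hypoxia in KPCS 528, and at 10.59 to 12.20 in all other libraries, and Eif2s3y at 5.97 to 6.31, at 9.13 and 9.11, and at 10.81 to 11.86. Number 530 thus had a female pattern of these sex-linked genes and the other lines a male pattern, with lower Y-linked values in KPCS 528. Hypoxic KPS holds a library of number 530 and normoxic KPS, as analysed here, holds none. Hypoxia in KPS without a block therefore cannot be told apart from this difference between lines. KPCS holds number 530 at both oxygen levels, and KP and KPC hold no line with this pattern.

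Each comparison of 3 against 3 libraries allows 10 splits, too few for a share below 0.05, so only the real count and the highest other count are given. These were 752 and 6 for hypoxia in KP, 488 and 0 in KPC, 288 and 0 for KPC against KP in normoxia, 1761 and 0 in hypoxia, 65 and 1 for KPCS against KPC in normoxia, 239 and 11 for KPS against KP in hypoxia, and 4 and 0 for the difference of Cre effects in hypoxia, each with the real split as the only 1 of 10 that reached its count. For hypoxia in KPCS they were 1222 and 893, also 1 of 10, where the split with 893 put both libraries of KPCS 520 with hypoxic KPCS 530 and so parts only 1 of the 3 lines. Among the 4 splits that part the libraries of all 3 lines, the highest other count was 0 in KP, KPC and KPCS. For both differences of hypoxia responses all 10 of 10 splits gave 0 genes.

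In 2 comparisons another split called several times the real count. For KPCS against KPS in hypoxia 5 of 10 splits reached 6 genes, and that of KPS 520, KPS 530 and KPCS 530 against the rest called 1736. For KPCS against KPC in hypoxia 2 of 10 reached 29, and that of KPC 571, KPCS 520 and KPCS 528 against the rest called 353. The highest counts were picked from all splits, and regrouping also changes the estimate of spread. A structure of the samples other than genotype was therefore not tested by these counts.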
